A study of Mus musculus with 2 samples.

How the data were processed

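RNA of E13.5 mouse facial prominence was measured in 2 libraries made, per the labels, from 10 ng of RNA over 200 nt extracted with the Ambion mirVana method. The labels list a spike-in reference, and 96 rows carry ERCC names. A document linked from the labels is the manual of the SMARTer Ultra Low RNA kit. Whether the libraries keep strand, and which aligner and quantifier were used, is not given in the sources used here, so counts of overlapping genes on opposite strands may share reads. The deposited notes name assembly mm10 and the GENCODE M4 annotation. The column names are those that RSEM writes, but no header or label names a program.

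Each library had a gene table and a transcript table. Expected counts and posterior mean counts, per the file headers, are the authors' estimated reads per feature and need not be whole. The deposited TPM values, per the file headers, are transcript abundances scaled to a total of 1000000 over all rows, spike-in rows included. The deposited upper credibility bounds of TPM are a signal in TPM whose sum is not fixed. The deposited FPKM values are fragments scaled by effective length and library total. The deposited posterior standard deviations of the counts were treated as a score. The deposited isoform percent columns give each transcript's share of its gene and were not needed, because shares were computed from transcript TPM. In every deposited transcript row with an effective length above 0 that length is the transcript length minus 99 nt, so TPM values of features barely longer than this are inflated by few reads. The notes that came with each library served only for the assembly and annotation.

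The gene tables had 69691 rows, of which 43346 have a gene identifier, 26248 a number only, 96 are ERCC spike-ins and 1 is phiX. Symbols, biotypes and coordinates came from GENCODE M21 on GRCm38, the same assembly as mm10, by gene identifier without version. Identifiers matched for 42462 rows and not for 884, and gene models can differ between releases M4 and M21. Spike-in, phiX and number-only rows stayed out of library sizes and tests. Spike-ins took 6.27% of the expected counts in replicate 1 and 4.45% in replicate 2, and number-only rows 0.000171% and 0.000151%. Because spike-in rows are in the TPM total (13.4% and 9.68% of it), TPM values of genes are lower than without them, and by more in replicate 1.

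Groups came from the labels: both libraries form 1 group. Before the data were examined, 35 gene lists (489 entries, 471 distinct genes, 468 matched to a row), 30 gene pairs, 20 genes for transcript usage, the tests, the alternatives and the rule for named genes were fixed. The rule took from each list its 2 to 4 highest genes by mean TPM, every pair, every transcript usage gene, the 10 highest nuclear protein-coding genes, the 5 highest genes of an RNA class, and the 10 largest differences between replicates among genes with a mean expected count of 100 or more. Not every gene or pair that the rule took is printed. Other genes are said to be named after their values were seen. The list genes Ahsp, Rn45s and Snhg1 matched no row.

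A gene was called detected at 1 TPM or more in both libraries. Each list's median of mean TPM was placed among medians of 10000 random lists of the same size, drawn with replacement from protein-coding genes. For differences between libraries, expected counts were rounded to whole numbers for edgeR 4.0.16 and DESeq2 1.42.0 in R 4.3.3, library sizes were scaled with TMM, and log2 ratios used a prior count of 1. List medians were placed among 10000 random lists matched on expression in 20 bins. The biological coefficient of variation came from edgeR with an intercept only after filterByExpr, with an interval from 50 bootstrap resamples of genes. Correlations used log2(TPM + 1), with 200 resamples of genes. Ratios of single genes carry exact Clopper-Pearson 95% intervals of the count in replicate 2 out of both, computed with scipy 1.17.1 in Python 3.11.15 and scaled by the effective library sizes. Shares of genes carry Wilson intervals. For a gene at 0 counts in a library the fold was computed against a floor of 3 counts, which leaves out counting error in the other library. A pair was called apart where the 95% credibility intervals of its genes did not overlap in either replicate and the order was the same. No test between conditions was possible, and no p-value is given.

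The steps were tested on simulated data. Counts drawn around the real means with a coefficient of 0.05, 0.1 and 0.2 gave 0.0498, 0.101 and 0.198 back. For the list comparison, counts of 43346 genes were drawn with 200 genes changed, and all 20 lists of 10 changed genes were called at 1.5-fold and at 4-fold. Of 100 unchanged lists, 7 and 3 were called at those folds, where 5% is the nominal rate. The simulated genes varied independently with 1 common dispersion, so these rates need not hold for lists of genes that vary together.

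Alternatives were other thresholds, units, pseudocounts, scalings, filters and backgrounds, and leaving out each replicate, 46 in all for the 8 planned results.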

Results

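RNA of the facial prominences of mouse embryos at embryonic day 13.5 (E13.5) was sequenced in 2 libraries. The facial prominences are the swellings of the embryonic head that give rise to the jaws, the nose and the palate, and consist of mesenchyme derived largely from the cranial neural crest under a surface epithelium. Both libraries belong to 1 group of pooled male and female embryos of the strain labelled B6NCrl. The labels number them as biological replicates 1 and 2, with separate biosample identifiers and 1 shared donor identifier, so the spread between them covers biosample and library together. The replicate 1 library held 30451502 expected counts, of which 28542452 were on gene rows. The replicate 2 library held 23777465, of which 22719352 were on gene rows. A count of 0 allows up to 0.105 CPM (counts scaled to a library total of 1000000) in replicate 1 and 0.132 in replicate 2 (3 counts of the library's gene-row total). Intervals cover counting error only, and a floor only that of the library at 0 counts, because reads without molecular identifiers are not independent molecules. A fold given as at least is taken against the floor and can exceed the exact lower counting limit. With 1 group there was no contrast between conditions. The results are levels in this tissue, given as the mean ± SD over the 2 libraries (n = 2) unless stated otherwise, and a comparison of the 2 libraries that has no replicate check and no p-value.

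TPM (length-corrected abundance scaled to a total of 1000000 in each library) reached 1 or more in both libraries for 14920 of 43346 gene rows. This held for 13016 of 21397 protein-coding genes other than histones, 49 of 64 replication-dependent histone genes, 959 of 6853 long non-coding RNA genes and 612 of 7906 pseudogenes. Protein-coding genes other than histones took 87.9% ± 0.893 of the expected counts, ERCC spike-in rows 5.36% ± 1.29, long non-coding RNAs 2.58% ± 0.00234, pseudogenes 1.75% ± 0.256 and mitochondrial genes 1.68% ± 0.121. The miscellaneous RNA class took 0.370% ± 0.0240 and replication-dependent histones 0.131% ± 0.00582. The miRNA, snoRNA, snRNA, scaRNA, ribozyme and rRNA classes each took at most 0.00408% in either library. The rRNA class holds only nuclear genes annotated as rRNA, so it is not the share of all ribosomal RNA. The mitochondrial gene mt-Rnr2 (127818 and 107759 counts in replicates 1 and 2) was counted as mitochondrial, and Rn45s matched no row. Of the 785421 and 612495 long non-coding counts, Gm42418 held 187962 and 152708 and Gm26917 held 210577 and 135279. These 2 genes lie next to each other on chromosome 17 (39846958 to 39848788 and 39843013 to 39846341). Their class was taken from the annotation alone. Whether their reads are long non-coding RNA or ribosomal RNA was not tested, so the long non-coding share may hold ribosomal RNA. The most abundant nuclear protein-coding gene was the alpha-globin gene Hba-a2 at 7092 ± 1604 TPM. It was followed by the actin gene Actb at 4636 ± 130.5, the translation elongation factor gene Eef1a1 at 4230.1 ± 41.9 and the ferritin light chain gene Ftl1 at 4133 ± 129.5. Next came Ppia at 4066 ± 7.71 TPM, the embryonic beta-globin gene Hbb-y at 3972 ± 77.9, the ribosomal protein gene Rpl41 at 3293 ± 48.5, Hba-a1 at 2909.8 ± 742, the ubiquitin gene Ubb at 2573 ± 94.7 and Ptma at 2542 ± 129. Among genes annotated as long non-coding RNAs, the nuclear RNA Malat1 was at 7773 ± 461 TPM, Gm42418 at 5298 ± 237, Gm26917 at 2839.5 ± 343, Gm37376 at 2544 ± 69.1 and Gas5 at 674 ± 59.5. Gm37376 lies within Malat1 on the opposite strand, and without known strandedness its reads were not separable from those of Malat1. The highest pseudogene was Gm28437 at 7338 ± 861 TPM, the highest mitochondrial gene mt-Atp6 at 6874 ± 1469 and the highest replication-dependent histone gene Hist1h2ap at 3239.8 ± 123. The signal recognition particle RNA rows Rn7s1 and Rn7s2 had identical values (13158 ± 1094 TPM each). Values of globin genes, pseudogenes, mitochondrial genes and ribosomal protein genes are uncertain where near-identical copies share reads.

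Genes of neural crest mesenchyme were expressed above most random gene lists. All 16 listed genes were at 1 TPM or more in both libraries, and the list's median of 66.6 TPM lay at percentile 100 (rounded) of 10000 random lists of protein-coding genes of the same size. The homeobox gene Msx1 (ENSMUSG00000048450.10, GRCm38 chromosome 5, 37820485 to 37824583) was at 419.8 ± 29.1 TPM, the paired-related homeobox gene Prrx1 at 137 ± 7.63, the chondrogenic factor Sox9 at 99.95 ± 27.0 and Snai1 at 91.8 ± 6.95. The fibrous matrix list had all 15 genes at 1 TPM or more and a median of 134.6 TPM, also at percentile 100. Its highest members were the collagen genes Col3a1 at 1113 ± 34.1, Col1a1 at 881 ± 92.9 and Col1a2 at 656 ± 28.7 TPM, and the matrix protein gene Postn at 290.5 ± 76.1. The palate and cleft list (16 of 16 genes at 1 TPM or more, median 27.8 TPM) was at percentile 99.03 of its random lists, with the odd-skipped genes Osr1 at 125 ± 2.38 and Osr2 at 111 ± 12.1 TPM. Altogether 13 of 35 lists lay outside the central 95% of random lists, 12 above and 1 below, where lists drawn at random give 1.75. The lists were chosen by what their genes are known for, some of them for abundance, so 1.75 is not the rate for such lists. Against random lists of genes detected in both libraries, 6 of the 12 (palate and cleft, cartilage, bone, epithelium, erythroid and hypoxia) lay within the central 95%, at percentiles from 76.1 to 97.4. With that background 8 further lists (tooth, neuron, pigment, lens, heart, pituitary, Wnt and Fgf), which include genes under 1 TPM, lay below it.

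**Figure D1:**
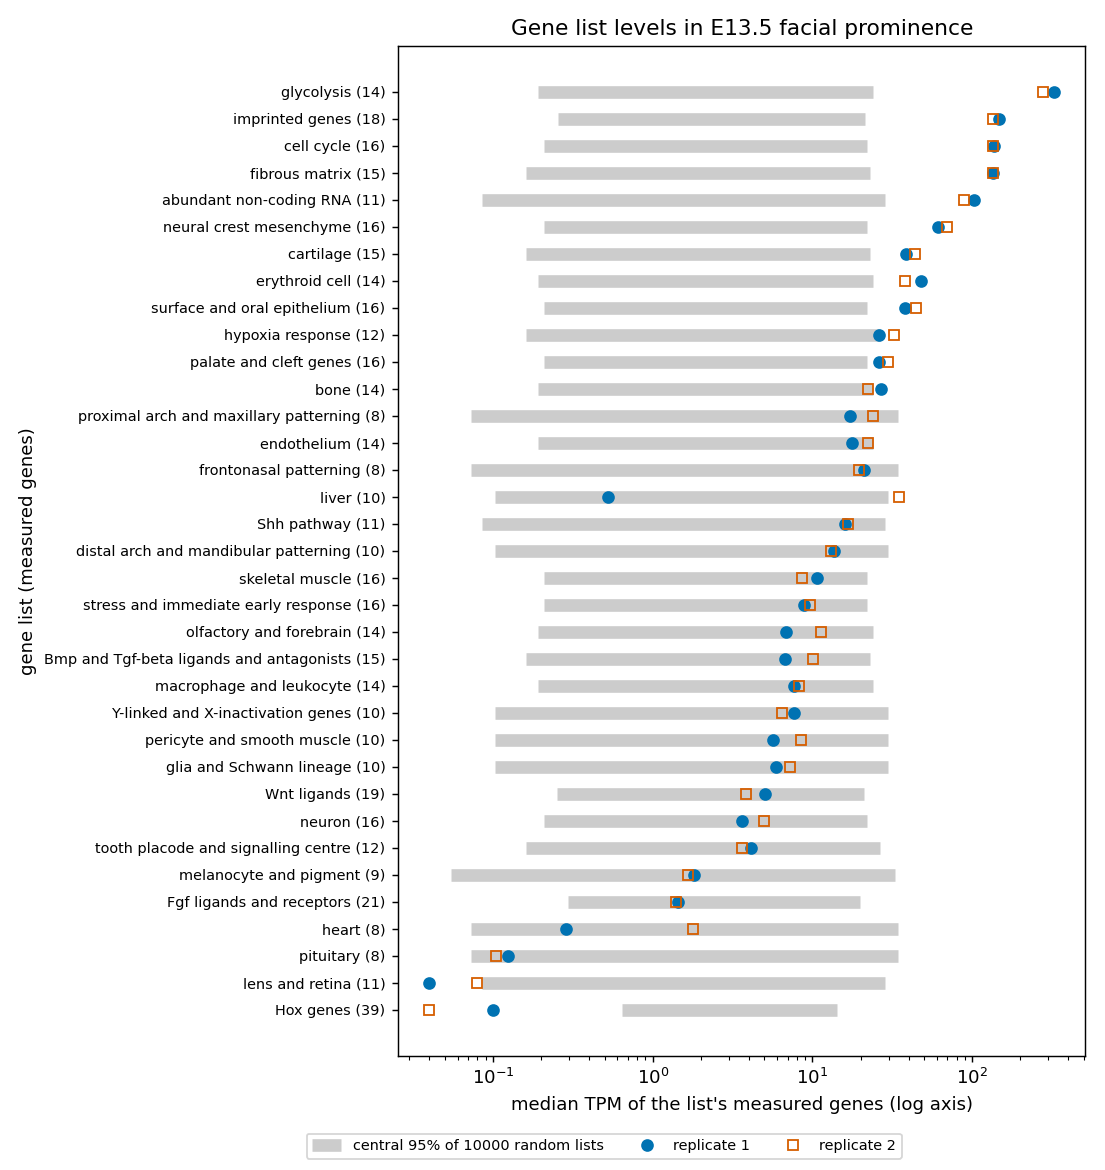
Median TPM of the measured genes of each of the 35 lists in replicate 1 (filled circles) and replicate 2 (open squares), on a log axis, with the central 95% of medians of 10000 random protein-coding lists of the same size as grey bars. Glycolysis (302 TPM over both libraries), imprinted genes (149 TPM) and cell cycle (136 TPM) lie right of the bars, the Hox genes lie left of them, and the liver list is at 0.525 TPM in replicate 1 and 34.9 TPM in replicate 2.

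Patterning genes of each prominence were detected, and Hox genes had a median of 0.10 TPM in replicate 1 and 0.040 TPM in replicate 2. The frontonasal list had 6 of 8 genes at 1 TPM or more in both libraries (median 20.2 TPM), led by the homeobox gene Alx1 at 251 ± 18.1 TPM. The proximal arch and maxillary list had 8 of 8 (median 20.7 TPM), with the LIM homeobox gene Lhx8 at 46.4 ± 1.27. The distal arch and mandibular list had 10 of 10 (median 13.4 TPM), with the endothelin receptor gene Ednra at 43.6 ± 0.417 and Dlx5 at 37.3 ± 4.91. These 3 medians lay within the central 95% of random lists. The median of the 39 Hox genes, which set position along the trunk and hindbrain, was 0.0750 TPM over both libraries, at percentile 0.03 (41.3 for its detected members alone), and 28 of them were under 1 TPM in both libraries. The 3 Hox genes at 1 TPM or more in both libraries were Hoxd1 (3.46 ± 0.827 TPM), Hoxd8 (2.35 ± 0.559) and Hoxd3 (1.83 ± 0.948, named after its value was seen). In replicate 1 alone 10 Hox genes were at 1 TPM or more, and in replicate 2 alone 4, these 3 and Hoxc13 (0.820 and 1.44 TPM, named after its values were seen).

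Skeletal and epithelial genes were abundant. In the cartilage list 14 of 15 genes were at 1 TPM or more (median 44.1 TPM, percentile 99.9), with the cartilage collagen genes Col2a1 at 263 ± 46.7 and Col9a3 at 185 ± 41.5 TPM. In the bone list 10 of 14 were (median 26.0 TPM, percentile 98.22, and 96.5 without replicate 1, within the central 95%), with Sparc at 985 ± 30.6 and the bone sialoprotein gene Ibsp at 239 ± 77.2. The other 4 bone genes, named after their values were seen, were the osteocalcin gene Bglap, its paralog Bglap2, the osteocyte gene Dmp1 and Phex, each under 1 TPM in at least 1 library. All 16 genes of surface and oral epithelium were detected (median 41.4 TPM, percentile 99.93), with the basal keratin genes Krt14 at 476 ± 44.7 and Krt5 at 342 ± 45.7. The tooth placode list (10 of 12, median 3.87 TPM) was led by the Wnt antagonist gene Sostdc1 at 148 ± 9.59 and Lef1 at 97.7 ± 7.99. The skeletal muscle list (15 of 16, median 9.77 TPM) was led by the cardiac actin gene Actc1 at 114 ± 39.0 and Tnnt1 at 45.8 ± 2.34. The medians of the tooth and muscle lists lay within the central 95% of random lists.

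Genes of other cell types were measured as well. Neuron genes (14 of 16 at 1 TPM or more, median 3.97 TPM) were led by Gap43 at 101 ± 13.1 and Stmn2 at 54.5 ± 6.34, and olfactory and forebrain genes (12 of 14, median 9.02 TPM) by Ebf1 at 55.3 ± 5.18 and Nrp1 at 40.1 ± 1.66. The glia and Schwann list (8 of 10, median 6.89 TPM) was led by Fabp7 at 21.8 ± 6.27, the pigment list (5 of 9, median 1.82 TPM) by Kit at 8.26 ± 0.778, and the lens and retina list (1 of 11, median 0.115 TPM) by Cryab at 10.6 ± 1.70. The lens list, with medians of 0.040 and 0.080 TPM in replicates 1 and 2, was at percentile 3.28 and left the central 95% without replicate 1 (2.17) or without replicate 2 (2.02). Endothelial genes (14 of 14, median 20.6 TPM) included Egfl7 at 69.1 ± 3.32 and Sox18 at 68.6 ± 1.09. Pericyte and smooth muscle genes (7 of 10, median 7.08 TPM) included Acta2 at 57.8 ± 2.28, and macrophage and leukocyte genes (14 of 14, median 8.02 TPM) included Lyz2 at 30.5 ± 3.0. The pituitary list (2 of 8, median 0.133 TPM) had Pitx1, also a gene of the lower jaw, at 34.1 ± 18.2 and Pomc at 2.70 ± 0.820 TPM. The heart list had 0 of 8 genes at 1 TPM or more in both libraries (median 1.04 TPM). Its median was 0.285 TPM in replicate 1, with 0 genes at 1 TPM or more, and 1.8 TPM in replicate 2, with 5 (Myh6, Myh7, Nppa, Nkx2-5 and Myl7, listed after their values were seen). The liver list had 2 of 10 in both, 2 in replicate 1 and 9 in replicate 2 (median 17.6 TPM, percentile 89.3). Its percentile was 10.8 without replicate 2 and 98.5, above the central 95%, without replicate 1. With both libraries all of these medians lay within the central 95% of random lists. The erythroid list (13 of 14, median 42.9 TPM, percentile 99.82) lay above it. The adult-type alpha-globin genes summed to 10001.7 ± 2346.5 TPM, the embryonic beta-globin genes to 4027 ± 52.1 and the adult-type beta-globin genes to 3759 ± 1310.4 TPM.

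Cell cycle genes (16 of 16, median 136 TPM) included Cdk1 at 323 ± 36.7 and Top2a at 209 ± 7.67 TPM, and glycolysis genes (14 of 14, median 302 TPM) included Gapdh at 1276 ± 175 and Eno1 at 1047 ± 58.7. Both medians were at percentile 100 of their random lists. The hypoxia list (11 of 12, median 29.3 TPM, percentile 98.4) was led by the glucose transporter gene Slc2a1 at 94.2 ± 4.35, and the stress and immediate early list (13 of 16, median 9.48 TPM, percentile 75.99) by Hspb1 at 98.4 ± 20.2. All 18 imprinted genes were detected (median 149 TPM, percentile 100), with Mest at 688 ± 12.5, Nnat at 628 ± 92.6 and Igf2 at 493 ± 16.2 TPM. The abundant non-coding RNA list, chosen for abundance, had 9 of 11 at 1 TPM or more (median 95.96 TPM, percentile 99.99 of random protein-coding lists). Shh pathway genes (10 of 11, median 17.0 TPM) were led by the receptor gene Gas1 at 151 ± 8.86. Bmp and Tgf-beta genes (15 of 15, median 8.39 TPM) included Tgfb2 at 67.4 ± 15.9, Wnt ligand genes (15 of 19, median 4.44 TPM) Wnt5a at 229 ± 27.1 and Wnt6 at 39.6 ± 2.95, and Fgf genes (12 of 21, median 1.58 TPM) the receptors Fgfr2 at 145 ± 14.0 and Fgfr1 at 122 ± 3.48. The medians of these 4 signalling lists lay within the central 95% of random lists. From the list of Y-linked and X-inactivation genes, 6 of 10 were at 1 TPM or more in pools of both sexes (median 7.09 TPM, within the central 95%), including Eif2s3y at 33.9 ± 6.77 and Xist at 27.7 ± 7.42 TPM.

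Of 30 gene pairs fixed in advance, 26 had 95% credibility intervals of TPM that did not overlap in either replicate, with the same gene higher in both. Of these, 21 also had a mean log2 ratio over 3 times its SD between replicates. The deposited intervals need not contain the TPM value that the ratios use. For the transcript Msx1-201 in replicate 1 the interval was 404.1 to 416.8, while its TPM was 421.55. Among patterning genes, Msx1 exceeded Msx2 by 3.93 ± 0.14 (log2), Alx1 exceeded Alx4 by 3.38 ± 0.24 and Dlx5 exceeded Dlx6 by 3.34 ± 0.12 and Dlx2 by 2.47 ± 0.04. Prrx1 exceeded Prrx2 by 0.77 ± 0.07, the anterior palate gene Shox2 exceeded the posterior palate gene Barx1 by 1.32 ± 0.33, and the log2 ratio of Twist1 to Twist2 was -0.70 ± 0.21. Among skeletal and muscle genes, Col2a1 exceeded Acan by 4.75 ± 0.12, Col1a1 exceeded Col2a1 by 1.75 ± 0.41, Myh3 exceeded Myh8 by 1.99 ± 0.37, and Myog exceeded Myod1 1.99-fold in each replicate. Among signalling genes, Wnt5a exceeded Wnt11 by 4.73 ± 0.28 and Fgfr1 exceeded Fgfr3 by 2.54 ± 0.22. Bmp4 exceeded Bmp2 2.84-fold in each replicate and Bmp7 by 0.62 ± 0.06 on the log2 scale. Tgfb2 exceeded Tgfb3 by 0.94 ± 0.21, the log2 ratio of Tgfb1 to Tgfb3 was -4.11 ± 0.10, and Gli3 exceeded Gli1 by 1.08 ± 0.31. Krt14 exceeded Krt5 by 0.48 ± 0.06, Meg3 exceeded Dlk1 by 1.36 ± 0.28, and Hba-a1 exceeded the embryonic gene Hba-x by 2.70 ± 0.41.

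In 5 pairs the intervals were apart but the ratio was not over 3 times its SD. The log2 ratio was -1.14 ± 0.48 for Hbb-bt to Hbb-y, 0.91 ± 0.44 for Dlx1 to Dlx2, 0.56 ± 0.34 for Runx2 to Sp7, -2.83 ± 1.04 for Krt8 to Krt5 and -0.25 ± 0.10 for Fgfr1 to Fgfr2. The order of Krt14 and Krt5, of Bmp4 and Bmp7 and of Fgfr1 and Fgfr2 turned when expected counts were not divided by transcript length. The other 4 pairs were not apart in both replicates. Among them, Hand2 to Hand1 was at 0.97 ± 0.26 (log2), Igf2 to the neighbouring H19 at 0.06 ± 0.17 and Osr2 to Osr1 at -0.18 ± 0.13.

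Transcript usage was compared between the libraries for genes with more than 1 annotated transcript and 5 TPM or more in both. The leading transcript was the same in 7293 of 7954 genes, or 91.7% (Wilson 95% interval 91.1 to 92.3, which treats genes as independent). Of 20 genes fixed in advance, 16 had the same leading transcript in both libraries. A single transcript carried most of the gene's TPM for Cdc42-202 (98.1% ± 0.0743), Msx1-201 (95.9% ± 0.246), Pkm-201 (94.9% ± 1.21), Col11a1-201 (74.2% ± 2.07), Tnc-204 (66.2% ± 0.682), Cd44-207 (56.5% ± 1.06), Col2a1-201 (55.4% ± 1.02) and Mitf-202 (52.4% ± 2.42). Shares of Mitf (gene TPM 1.81 and 2.09) and Pax6 (1.18 and 2.51) rest on low levels. The leading share was 42.4% ± 2.24 for the Tpm1 transcript ENSMUST00000113697.3, 38.8% ± 13.2 for Fgfr3-211, 37.1% ± 5.72 for Prrx1-201, 36.7% ± 2.76 for Pax6-202 and 36.4% ± 1.17 for Gas5-210. It was 35.5% ± 9.17 for Fgfr1-202, 34.7% ± 2.16 for Ctnnd1-202 and 26.8% ± 0.962 for Runx2-202. The leading transcript differed between libraries for Fn1, Trp63, Fgfr2 and Meis2, whose highest mean shares were 36.7% ± 3.22, 32.0% ± 4.81, 25.4% ± 2.00 and 23.6% ± 13.4.

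Across genes, the 2 libraries correlated with a Pearson r of 0.990 on log2(TPM + 1) and a Spearman rho of 0.943 over 43346 gene rows, which are not independent replicates. Of the 14920 genes at 1 TPM or more in both, 14444 (96.8%) lay within 2-fold, 405 were over 2-fold higher in replicate 2 and 71 in replicate 1. Of the 13065 protein-coding genes among them, histones included, 98.9% lay within 2-fold, with 108 higher in replicate 2 and 32 in replicate 1. These are ratios of TPM, whose totals include spike-in rows (13.4% in replicate 1 and 9.68% in replicate 2). The common biological coefficient of variation was 0.134 (edgeR, 16903 genes, bootstrap interval over genes 0.126 to 0.140), and 0.102 over protein-coding nuclear genes alone. A chi-square test asked only whether 1 library had been deposited under both labels. Of 17726 genes, 39.5% lay beyond its 95% limit, where 1 library sampled again gives 5%, so the libraries were counted separately. Spike-in scaling in place of TMM scaling shifted the scale of log2 ratios of replicate 2 over replicate 1 by 0.538, and the ratios of genes with few counts by less (Fga from 8.51 to 8.83), because of the prior count. Ratios between the libraries are therefore relative to the bulk of genes under TMM scaling.

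**Figure D2:**
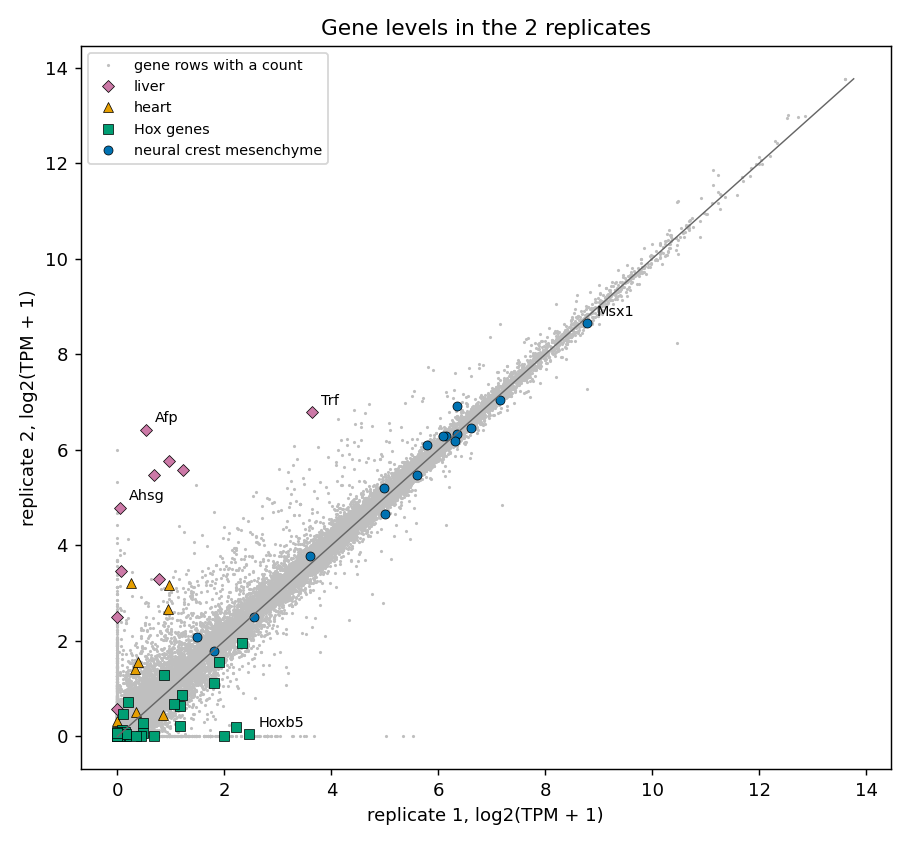
Gene levels in replicate 1 (horizontal) and replicate 2 (vertical), both as log2(TPM + 1), for all gene rows with a count, with the diagonal as a line and 4 lists coloured. Mesenchyme genes lie near the diagonal, liver genes such as Afp (0.450 and 84.7 TPM) lie above it, and Hoxb5 (4.52 and 0.0300 TPM) lies below it.

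Liver genes were higher in replicate 2. All 10 liver genes were higher in replicate 2 beyond their 95% counting intervals, and the list's median log2 ratio was 5.73 (5.91 without the prior count and with the 2 genes at 0 counts in replicate 1, Fgb and Hnf4a, at the floor), against -0.15 to 0.19 for the central 95% of random lists matched on expression. The alpha-fetoprotein gene Afp (ENSMUSG00000054932.3, chromosome 5, 90490737 to 90508907) had 19 counts in replicate 1 and 2714 in replicate 2, a 177-fold difference in CPM (95% counting interval 113 to 295). The neighbouring albumin gene Alb had 55 and 1457 counts (32.9-fold, 25.1 to 43.9), Apoa1 19 and 799 counts (52.2-fold, 33.2 to 87.2), and the transferrin gene Trf 451 and 3600.1 counts (9.92-fold, 8.99 to 11.0). The fibrinogen genes Fga and Fgb had 0 counts in replicate 1 and were at least 134-fold and 115-fold higher in replicate 2, against a floor of 3 counts per library. Their exact lower 95% counting limits were 108.5-fold and 92.7-fold. Kng1, at 0.340 expected counts in replicate 1, was at least 95.3-fold higher. Fgg had 1 and 331 counts (411-fold, 73.3 to 16289), Ahsg 1 and 591 (734-fold, 131 to 29046), Ambp 1 and 265 (329-fold, 58.6 to 13051) and Serpina1a was 249.7-fold higher (44.3 to 9910.5). Of the heart list, 7 of 8 genes were higher in replicate 2 beyond counting error and the other, Tbx5, was 2.31-fold higher in replicate 1 (1.42 to 3.89, named after its values were seen). The list's median log2 ratio was 2.5 (5.67-fold), against -0.28 to 0.52 for random lists. Among the 7 were Nppa at 3 and 102 counts (42.2-fold, 14.1 to 208) and the myosin gene Myh7 at 117 and 522 counts (5.54-fold, 4.53 to 6.83).

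The median Hox gene was higher in replicate 1. Of the 32 with a count, 13 were higher in replicate 1 beyond counting error and 3 in replicate 2, with a median log2 ratio of -0.94 (-1.01 over the 21 genes above the floor, without the prior count and with those at 0 counts in a library at the floor), against -0.22 to 0.63 for random lists. Under spike-in scaling the median was -0.58. Hoxb5 (chromosome 11, 96303336 to 96306121) had 174 counts in replicate 1 and 1 in replicate 2, 140-fold higher in replicate 1 (24.8 to 5564). Hoxa5 had 137 and 4 counts (27.6-fold, 10.5 to 103). Hoxb6, named after its values were seen, had 84 and 0 counts and was at least 22.5-fold higher in replicate 1.

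Altogether 14 of 35 lists had a median log2 ratio outside the central 95% of matched random lists, 7 in each direction, where lists drawn at random give 1.75. Genes of 1 list can vary together between libraries, and some lists share members, so 1.75 is not the rate for such sets. Besides liver and heart, the lists higher in replicate 2 were erythroid (0.47), olfactory and forebrain (0.46), cartilage (0.27), neuron (0.21) and endothelium (0.10). The cartilage genes Col2a1 (1.20-fold, 1.18 to 1.23) and Cnmd (1.41-fold, 1.33 to 1.49) and the neuronal gene Elavl4 (1.80-fold, 1.54 to 2.11) were higher in replicate 2. Besides Hox genes, the lists lower in replicate 2 under TMM scaling were distal arch (-0.30), bone (-0.29), skeletal muscle (-0.22), glycolysis (-0.17), Wnt ligands (-0.15) and neural crest mesenchyme (-0.12). Under spike-in scaling these 6 medians were positive, from 0.24 for distal arch to 0.41 for mesenchyme, while the percentiles among random lists stayed below the central 95%. The mesenchyme list was within it (percentile 3.80) with TPM and a pseudocount of 1. In the mesenchyme list 7 genes were higher in replicate 1 and 5 in replicate 2 beyond counting error under TMM scaling. Ibsp was 1.68-fold higher in replicate 1 (1.63 to 1.74) and Pitx1 2.29-fold (2.10 to 2.49), both also by more than the shift under spike-in scaling.

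**Figure D3:**
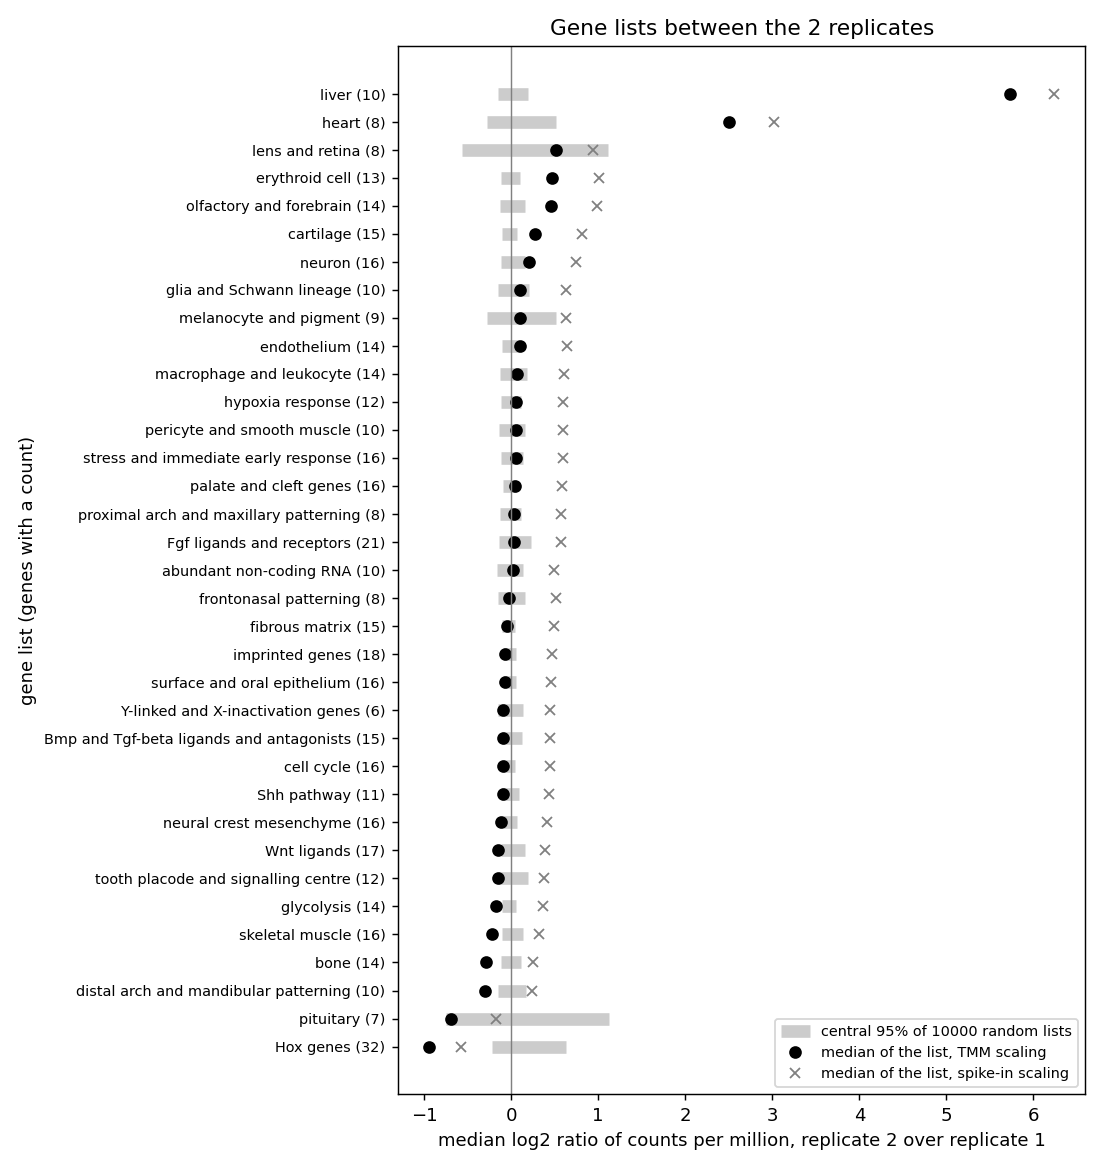
Median log2 ratio of CPM, replicate 2 over replicate 1, of each list under TMM scaling (circles) and spike-in scaling (crosses), with the central 95% of 10000 expression-matched random lists under TMM scaling as grey bars. Liver (5.73) and heart (2.5) lie farthest right and Hox genes (-0.94) farthest left, and the 6 other lists left of their bars under TMM scaling, such as bone (-0.29), have positive medians under spike-in scaling.

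Of 12730 genes with a mean expected count of 100 or more, 145 were over 2-fold higher in replicate 2 and 21 in replicate 1. Relative to the TMM scale, these included 83 and 2 of 230 pseudogenes, with a median log2 ratio of 0.45, and 59 and 15 of 12003 protein-coding genes other than histones, with a median of -0.01. The pseudogenes Rpl30-ps9 and Rpl30-ps10, both on chromosome X, went opposite ways, with 0 and 250.3 counts (at least 104-fold higher in replicate 2) and 207 and 0 counts (at least 55.5-fold higher in replicate 1). These are copies of 1 ribosomal protein gene, and how the quantification divided shared reads between them is uncertain.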

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

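Rows of the gene tables that carry a number and no gene identifier were outside every comparison and still held expected counts. They summed to 52 counts in replicate 1 and 36 in replicate 2, or 0.000171% and 0.000151% of the expected counts. In each library 8 of the 26248 such rows had a count, 6 of them in both, and the highest row had 39.0 counts in replicate 1 and 22.0 in replicate 2. What these rows stand for is not given in the sources used here.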

How the results depend on the processing

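All alternatives were planned before the data were examined. The number of detected genes, the counts of gene lists outside the random range, for levels and for differences between replicates, and the count of pairs apart stayed within 1.5 times under every alternative but 1: with a ratio over 2-fold in both replicates required, 15 pairs were apart in place of 26, because the criterion is stricter. Leaving out a replicate gave 15384 to 16037 detected genes, 14 to 14 lists outside the range of levels, 26 to 30 pairs apart and a protein-coding share of 87.3% to 88.5%. The correlation of the replicates left its interval of 0.989 to 0.990 under each of its alternatives: 0.979 with pseudocount 0.1, 0.994 with pseudocount 10, 0.987 over genes at 1 TPM or more, 0.994 over protein-coding genes, 0.991 with FPKM, 0.968 with transcript TPM and 0.993 with posterior mean TPM; the cause was not tested. The biological coefficient of variation was 0.317 with spike-in scaling, which adds its 0.538 shift of the log2 scale to the spread, 0.180 with no filter on low counts, 0.124 over genes with a mean count of 100 or more and 0.102 over protein-coding nuclear genes, the last 3 over other sets of genes. With DESeq2 size factors it was 0.133. The share of protein-coding genes was 73.1% of TPM, which weights short transcripts more. Other classes took larger shares of TPM than of counts, among them ERCC spike-in rows 11.55%, pseudogenes 5.51%, mitochondrial genes 3.04%, miscellaneous RNA 2.70%, replication-dependent histones 0.470% and miRNA 0.418%. Most of the miRNA share was 1 row, Gm22133, at 3521 ± 139 TPM from 766 and 552 counts in replicates 1 and 2. It lies within Ftl1 on the same strand, so its reads may be those of Ftl1. The share of genes with the same leading transcript was 89.4% at 1 TPM or more and 93.7% at 20 TPM or more; the cause was not tested. The log2 ratio turned to -0.11 for Krt14 to Krt5, to -0.13 for Bmp4 to Bmp7 and to 0.22 for Fgfr1 to Fgfr2 with expected counts not divided by length, which favours longer transcripts. Of 208 alternatives for the levels of single lists, 188 kept their side of the random range, 12 moved outside it and 8 moved inside. Of 173 for list differences between replicates, 168 kept their side, 4 moved outside and 1 inside. With spike-in scaling the difference percentile of the abundant non-coding RNA list was 32.65 in place of 70.0, inside the random range both times. Agreement, variation and list differences cannot be computed without a replicate. Depth limits single-gene ratios to counting intervals, and no interval covers variation between embryos.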

Other observations

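The tests of more blood and of genomic DNA, the hepatocyte share without the prior count and all genes named first here, were chosen after their values were seen. The further marker lists were written after the patterns were seen and before their tests, without the genes that showed the pattern. Leaving those genes out can lower the shares, so a share short of the one set for a tissue cannot argue against its RNA. Some intestinal genes, chosen for having 0 counts in replicate 1, were counted in replicate 2: the bile acid binding protein gene Fabp6 had 0 and 125 counts (20.4 TPM in replicate 2, at least 51.8-fold higher), the antimicrobial lectin gene Reg3b 0 and 126 (at least 52.2-fold), Zg16 0 and 103 (at least 42.6-fold) and the mucin gene Muc3 0 and 93 (at least 38.5-fold). The ventricular myosin light chain gene Myl2 had 0 and 196 counts (24.6 TPM, at least 81.2-fold), and the myeloid granule genes Mpo and Ngp were 3.88-fold (2.80 to 5.44) and 6.40-fold (3.94 to 10.9) higher in replicate 2. In replicate 1 the neural homeobox genes Lhx1 (55 and 3 counts, 14.8-fold, 4.79 to 73.8) and Tlx3 (29 and 1 counts, 23.4-fold, 3.87 to 954) were higher. So were the surfactant gene Sftpc (48 and 2 counts, 19.3-fold, 5.07 to 164), Sst (2.95-fold, 2.35 to 3.74) and the long non-coding RNA Hand2os1 (3.69-fold, 3.13 to 4.38). The keratin gene Krt1 was 1.83-fold higher in replicate 1 (1.69 to 1.99). Xist was 1.38-fold higher in replicate 2 (1.34 to 1.42) and the Y-linked gene Eif2s3y 1.27-fold higher in replicate 1 (1.15 to 1.41). The direction of Eif2s3y turned under spike-in scaling, which shifts the log2 scale by 0.538.

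Liver genes, part of the intestinal genes and all heart list genes but Tbx5 were higher in replicate 2. Examples there were the liver genes Trf at 110 TPM and Afp at 84.7 TPM, the intestinal gene Fabp6 at 20.4 TPM and the heart gene Myl2 at 24.6 TPM. With 1 group there was no contrast of conditions to test an explanation of this or the next patterns. The explanations below were set only against other genes of the same 2 libraries. Summed globin CPM was 0.34 (log2) higher in replicate 2, from -0.19 for embryonic alpha to 0.68 for adult-type beta, so more blood there stays possible. As the source of the liver genes it is argued against, since the median liver gene differed by 5.73. RNA of liver may be present. Of 12 further hepatocyte genes with 10 or more counts, led by Apoc1 at 7.87 and 13.55 TPM, 33.3% were 4-fold or more higher in replicate 2 (Wilson interval 13.8 to 60.9). Without the prior count 6 of 12 were (25.4 to 74.6), and with it none was 4-fold lower. RNA of intestine may also be present: of 18 further intestinal genes, led by Reg3g at 5.03 and 16.95 TPM, 50% were 4-fold or more higher in replicate 2 (29.0 to 71.0). These shares lay between those set for and against each tissue. Because the lists left out the genes that showed the pattern, the shares cannot decide, and RNA of liver and of intestine both stay open. In replicate 1, 2 of the 19 measured hepatocyte genes and 7 of the 20 intestinal genes were at 1 TPM or more, and for these genes alone a baseline can hide a small share. Whether RNA of liver or intestine came with the dissection or from another library was not tested.

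Hoxa5, Hoxb5 and Hoxb6 were higher in replicate 1. RNA of hindbrain or spinal cord may be present: of 14 further genes of these tissues with 10 or more counts, 28.6% were 2-fold or more higher in replicate 1 (11.7 to 54.6) and none was 2-fold lower, between the shares set for and against it. The highest of these genes, En1, was at 2.04 and 2.16 TPM, and 3 of the 20 were at 1 TPM or more in replicate 1. RNA of lung was tested with 5 further genes with 10 or more counts, led by Etv5 at 22.75 and 23.96 TPM (3 of 10 at 1 TPM or more in replicate 1), of which 0.0% were 2-fold or more higher in replicate 1 (upper limit 43.4), too few genes to exclude it.

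Processed pseudogenes with 200 or more counts were higher in replicate 2, with 81 of 196 over 2-fold higher, 1 over 2-fold lower and a median log2 ratio of 0.76, while 28 unprocessed pseudogenes had a median of 0.10. Genomic DNA in replicate 2 is argued against as the whole cause: genomic reads would cover the 493 vomeronasal receptor genes as well, and these had 3.26e-05 extra reads per kilobase (bootstrap interval -0.0430 to 0.0450), against a median of 302 (190.0 to 394) over all 196 processed pseudogenes. Reads of near-identical copies divided differently may contribute, but the posterior standard deviation over the root of the count was 1.14 times that of the other processed pseudogenes (0.947 to 1.32), between the values set for and against it. This stays open.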
